A study of Gallus gallus with 2 samples.

How the data were processed

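The 2 libraries used were 1 from the injected right wing and 1 from the uninjected left wing of 1 chick embryo overexpressing SOCS2. Per the labels' protocols, total RNA was extracted from each wing with a column kit and DNase treatment, 1 µg went into an NEBNext Ultra library, and paired-end reads were sequenced on an Illumina instrument. The series' design text names the NovaSeq platform. The values are TPM as the authors deposited them, in a table of 24356 rows with Ensembl chicken identifiers, in which both libraries have the same sum. The submitters' processing notes name HISAT2 2.2.1, StringTie 2.1.7 and the genome build GRCg6a; the role and settings of each tool, the annotation release, read trimming and strand settings are not given in the sources used here. TPM is scaled within each library, so a rise in abundant genes lowers all others, and short genes carry more error than long genes of equal TPM.

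A table of raw counts was not used. Its 2 columns carry names that match neither sample's title, and its gene identifiers follow another annotation. Whether these columns come from another embryo is not given in the sources used here, so they served as no replicate. The planned analysis assumed counts, with an interval for counting error. TPM allows no such interval, so the alternative planned for TPM became the main result, and the depth of the libraries is unknown.

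For each gene the log2 ratio of injected over uninjected was computed as log2(TPM + 0.1) in the injected wing minus the same in the uninjected wing, which understates the change of genes with low values. A gene was compared if its mean was at least 1 TPM and it was above 0 in both libraries. Of the rows, 12560 had a symbol, 10487 had none and 1309 were short RNAs, which were left out, a choice made after the data were examined because the library kit targets longer transcripts. A value of 0 was listed in both libraries for 5302 rows, in the uninjected library alone for 987 and in the injected library alone for 816. A zero can be a failed estimate, so no ratio is given for such rows. This left 13946 genes, 10976 of them with a symbol. A gene was called higher or lower when its ratio passed 1.5-fold, which is a rule of size on 2 libraries and not a test of the conditions. Each group held 1 library, so no p-value, standard deviation or standard error was computed.

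Before the data were examined, 29 gene lists (743 entries) were fixed for pathways, skeletal tissues, markers of other cell types and RNA quality. Entries were matched to the symbols in the table, or to older symbols through a RefSeq gene table of assembly GRCg7b, used for names alone. Of the entries, 665 matched, 12 of them by an older symbol, and 634 were measured. Older symbols can join different genes; the matches of TFRC to TFR2 and of LBR to TM7SF2 are doubtful, and neither gene is named in the results. For each list the median log2 ratio was computed with an exact 95% interval from order statistics over genes. Its percentile was taken among 10000 random lists of the same size, drawn within 20 bins of mean TPM. Lists share some genes, such as OSR1 in joint interzone and connective tissue.

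Genes were named by a rule fixed beforehand: SOCS2 and the SOCS family, 12 higher and 12 lower genes with a symbol, up to 3 called members of each list in each direction, and the 2 most abundant members of a list with 0 calls. The rule ranked genes by the bound of the counting interval. As TPM has none, the ratio of TPM + 1 was used for ranking, a replacement chosen after values were seen. Some genes that the rule names are not reported here. Genes outside the rule are said to be so where they are named. The grouping of Hox genes and the lists of distal and proximal limb genes, complex I, mitochondrial ribosomal proteins and histones were made after the data were examined.

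The calls and list percentiles were run on simulated data over 13946 genes. Each gene varied independently, with normal noise centred on 0. Its spread was set from the median absolute deviation of the log2 ratios in the gene's abundance bin. That spread came from these same 2 libraries, so the simulation gives no rate of false calls. The shares recovered hold for such noise only. Of 50 genes changed 2-fold, 96.0% were recovered, as were 100% of 50 genes at each of 3-, 4- and 6-fold. Alternatives planned beforehand were 3 other scalings (median of ratios, upper quartile and trimmed mean), no filter, a minimum mean of 5 TPM, a 2-fold rule, and removal of the trend of the ratio over abundance. Added after the data were examined were pseudocounts of 1 and 0.01 TPM, keeping short RNAs, and genes with a symbol only. No genome sequence was used, so GC content and transcript length were not analysed here. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.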

Results

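Messenger RNA was sequenced from the wings of 1 chick embryo in which SOCS2, a suppressor of cytokine signalling known to dampen growth hormone signalling, had been overexpressed. The right wing had been injected with RCAS, a replication-competent avian retrovirus, carrying GFP and SOCS2, and the left wing of the same embryo was not injected. RNA was taken from each wing 5 days after infection, at stage HH 34 of the Hamburger-Hamilton series of chick development, when the digits are forming. Each group held 1 library among those used here, so the difference between wings had no replicate check and no p-value was computed. Injected against uninjected was also right against left. Expression was given in TPM, a measure of transcript abundance corrected for length and scaled to the same total in each library, which keeps no record of read depth, so the depth of the libraries was unknown and no counting interval was given. Over all rows, short RNAs included, the 10 most abundant held 5.79% of the TPM in the injected wing and 5.90% in the uninjected wing. In these wings, 14054 and 14162 rows reached 1 TPM.

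The first question was whether the injected wing carried more SOCS2 transcript. SOCS2 (ENSGALG00000050619) was at 54.2 TPM in the uninjected wing and 254 TPM in the injected wing, which was 4.69-fold higher, or 2.23 on the log2 scale. This was the highest ratio among the 7881 genes with a mean of at least 20 TPM. The next highest, 1.72 on the log2 scale, belonged to a row with no gene symbol. The table has 1 SOCS2 value per wing and does not separate transcripts of the vector from those of the embryo's own gene. Of the 8 measured members of the SOCS family, SOCS2 was higher and SOCS3, a feedback inhibitor of interleukin-6 type cytokine signalling, was lower, from 6.06 to 3.86 TPM (log2 ratio −0.64). The other 6 lay within 1.5-fold. CISH, a feedback inhibitor induced through STAT5, was at 20.7 TPM in the uninjected and 20.4 TPM in the injected wing. The log2 ratios were 0.57 for SOCS1, −0.00 for SOCS4, −0.35 for SOCS5, −0.03 for SOCS6 and 0.11 for SOCS7. The calls of SOCS1 and SOCS3 depended on the setting: SOCS1 passed 1.5-fold at 0.65, and SOCS3 no longer did at −0.55, once the trend of the ratio over abundance was removed.

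The second question was how far the rest of the transcriptome differed between the wings. Of 13946 genes compared, 311 (2.23%) were higher and 668 (4.79%) lower in the injected wing by more than 1.5-fold, while 12967 (93.0%) lay within that range. The median log2 ratio was −0.04, and the 5th and 95th percentiles were −0.57 and 0.40. Across genes, log2 TPM in the 2 wings had a Pearson r of 0.988, where genes are not independent replicates. Beyond 2-fold there were 70 higher and 207 lower genes. The share beyond 1.5-fold was 23.2% of the 2431 genes with a mean of 1 to 5 TPM and 1.87% of the 1817 genes above 100 TPM. In data simulated with normal noise centred on 0, 513 of 13746 unchanged genes (3.73%) passed the 1.5-fold rule. The spread of the noise was set from the median absolute deviation of the observed ratios. That spread came from these same 2 libraries, can hold differences between the wings and gives little weight to extreme genes, so 3.73% is no rate of false calls. Genes higher made up 31.8% of the calls. With the trend of the ratio over abundance removed, the split became 430 higher and 524 lower, or 45.1% higher.

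**Figure D1:**
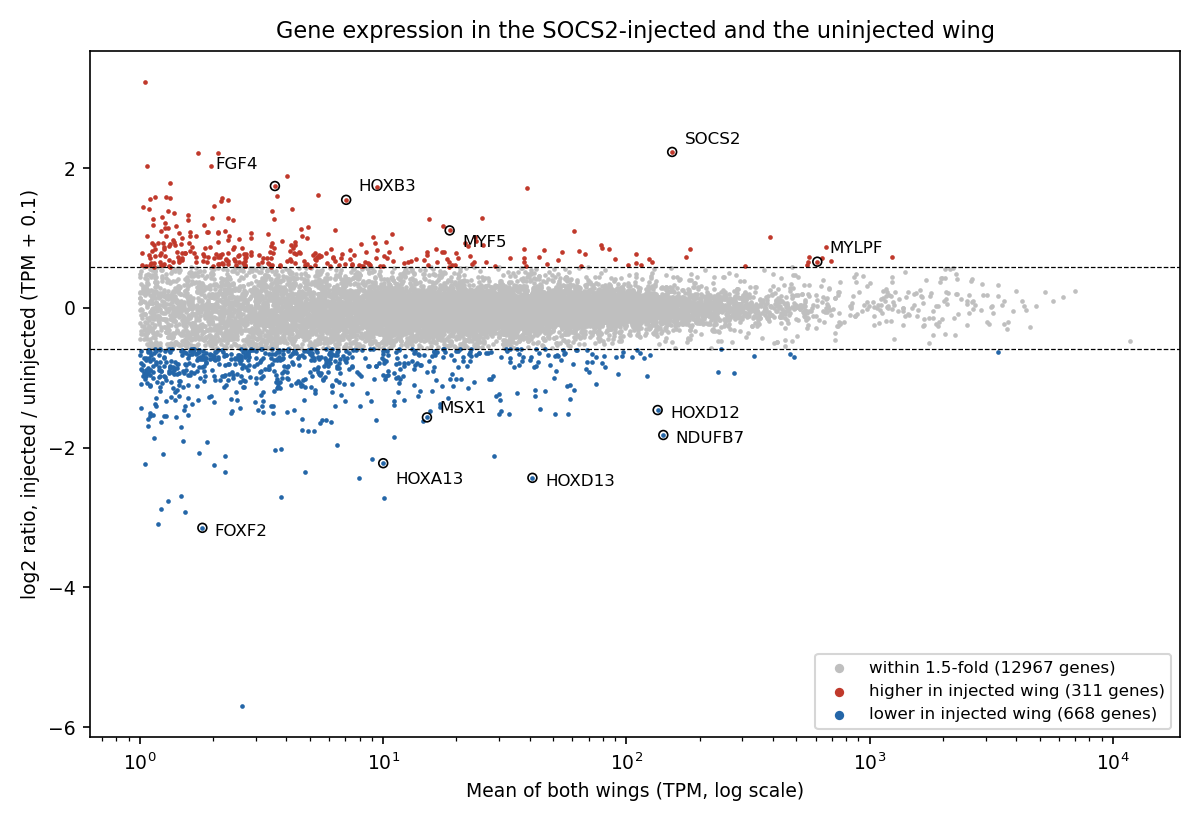
The log2 ratio of injected over uninjected wing, computed as TPM + 0.1, is plotted for each of the 13946 genes compared (points) against the mean of both wings in TPM on a log axis, with dashed lines at 1.5-fold. The 311 higher genes are red and the 668 lower genes blue, SOCS2 lies at 2.23 with a mean of 154 TPM, and HOXA13 and HOXD13 lie at −2.22 and −2.43.

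After SOCS2, the genes with symbols that ranked highest in the injected wing were of several kinds. HOXB3, a Hox gene of the anterior part of the cluster, went from 3.55 to 10.5 TPM (log2 ratio 1.54) and HOXC4 had a ratio of 1.57. FGF4, a growth factor of the apical ectodermal ridge that caps the limb bud, went from 1.60 to 5.58 TPM (1.74). Cbln2, a secreted cerebellin family protein, went from 9.03 to 21.8 TPM (1.26), and PPP1R14B, an inhibitor of protein phosphatase 1, went from 38.9 to 83.3 TPM (1.10). Also in this group were the beta-defensin AvBD2 (2.21), the tight junction gene CLDN14 (2.22), PSCA (1.61), LECT2 (1.60) and the angiotensinogen gene AGT (1.38), each with a mean under 6 TPM. With a pseudocount of 1 TPM the ratios of AvBD2 and CLDN14 were 1.43 and 1.34, against 2.21 for SOCS2.

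Among the lower genes, HOXD13 and HOXA13, transcription factors of the hand and foot region, were at 69.4 and 16.5 TPM in the uninjected and at 12.8 and 3.46 TPM in the injected wing, with log2 ratios of −2.43 and −2.22. NRN1, which encodes the neurite growth protein neuritin, went from 14.8 to 3.21 TPM (−2.17), and FOXF2, a forkhead transcription factor, from 3.33 to 0.29 TPM (−3.15). Mitochondrial proteins were also in this group: NDUFB7, a subunit of respiratory complex I, went from 221 to 62.6 TPM (−1.82), MRPS12, a protein of the mitochondrial ribosome, from 48.9 to 17 TPM (−1.52), and OPA3 from 17.3 to 4.76 TPM (−1.84). The others were ALC (−2.72), the prostaglandin D2 receptor gene PTGDR (−2.35), Nnf1 (−1.52), C1orf145 (−1.62) and HIST1H46L2 (−2.44). The last belongs to a histone family of near-identical copies, among which reads are hard to assign. With a pseudocount of 1 TPM, FOXF2 was at −1.75 and PTGDR at −1.53.

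Genes of digit and limb patterning differed in both directions. Of 34 measured, 7 were lower, 3 higher and 24 within 1.5-fold. MSX1, a homeobox gene of the distal limb mesenchyme, went from 22.7 to 7.59 TPM (−1.57) and joined HOXD13 and HOXA13. The other 4 lower members, named after their values were seen, were HOXD12 at 197 and 71.5 TPM (−1.46), SALL1 (−1.42), MSX2 (−0.99) and HOXD11 (−0.79). FGF8, also expressed in the apical ridge, went from 5.56 to 10.6 TPM (0.92), and Meis2a.2, the listed name for MEIS2, a homeobox gene of the proximal limb, from 33 to 58.6 TPM (0.82). FGF4 was the remaining higher member. The median of the list was −0.11 (95% interval over genes −0.34 to 0.07), at percentile 2.94 of 10000 random lists matched on abundance, just inside their central 95%.

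A grouping of the Hox genes by paralogue group was made after these values were seen. In groups 11 to 13, HOXD11, HOXD12, HOXD13 and HOXA13 were lower and HOXA11, at 36.8 and 25.6 TPM, was not (−0.52); the median of these 5 was −1.46. The 20 genes of groups 1 to 8 had a median of 0.39 (95% interval 0.03 to 0.80), with 8 higher and 0 lower. The 7 genes of groups 9 and 10 had a median of −0.00, and HOXC9 alone among them was lower. Within groups 1 to 8 the higher genes came from clusters B and C. HOXB2, HOXB3, HOXB4, HOXB5 and HOXB7 were 5 of 7 in cluster B (median 0.80), and HOXC4, HOXC6 and HOXC8 were 3 of 3 in cluster C (1.06). The 7 genes of cluster A had a median of 0.03 and the 3 of cluster D one of 0.10, with 0 called in either.

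**Figure D2:**
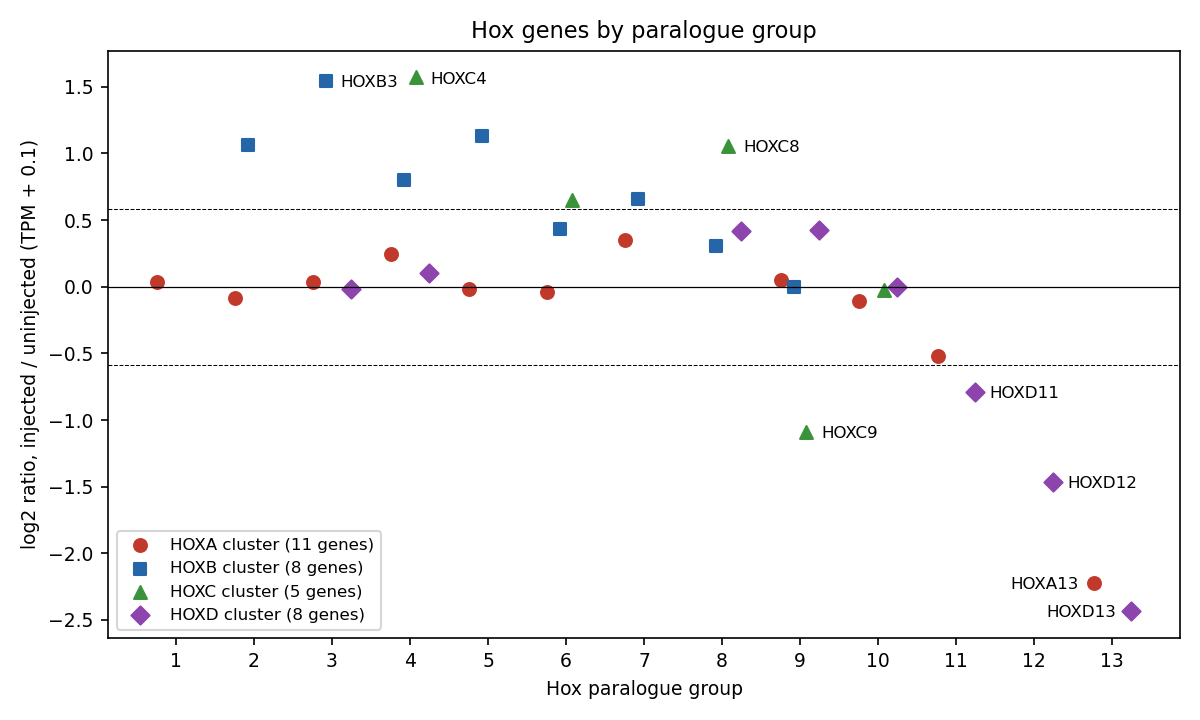
The log2 ratio of injected over uninjected wing (TPM + 0.1) is plotted for the 32 Hox genes compared (points, coloured and shaped by cluster) against paralogue group, with dashed lines at 1.5-fold. The ratios run from 1.57 for HOXC4 to −2.43 for HOXD13.

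Other signalling lists bearing on the digits held few calls. SHH, known as the posterior signal of the limb bud but not traced to a tissue here, was lower at 6.35 and 2.87 TPM (−1.12), 1 of 14 hedgehog genes. The median of that list was −0.15, at percentile 2.86, and it left the central 95% of random lists when the abundance trend was removed. Of 33 genes of BMP and TGF-beta signalling, ID1, a target of BMP signalling, was lower at 41 and 17 TPM (−1.27), as were the ligand gene TGFB1 (−0.76) and the BMP pseudoreceptor gene BAMBI (−0.67); the list median was −0.06, at percentile 24.5. The WNT antagonist DKK1 was lower at 6.01 and 2.07 TPM (−1.49), the only call among 24 WNT genes (median −0.04, percentile 43.2). FGF13 was higher (0.72) among 23 further FGF signalling genes (median 0.02, percentile 91.0). The death receptor gene FAS was higher (0.86), among 25 genes of interdigital cell death and retinoid signalling (median −0.04, percentile 42.7).

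Hindlimb identity genes, which mark the leg rather than the wing, had 2 of 4 members lower. TBX4 went from 5.25 to 1.79 TPM (−1.50) and HOXC9 from 10.2 to 4.74 TPM (−1.09). PITX1, named after its value was seen, was at 15.2 and 15.3 TPM. The median of −0.56 lay at percentile 1.46, and without a filter on low values it was −0.18 and inside the random range.

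In growth hormone, IGF and JAK-STAT signalling, the pathways that SOCS proteins act on, 2 of 34 measured genes passed 1.5-fold. IGF-I was higher, from 2.04 to 5.06 TPM (1.27), and IGF2 was lower, from 30.2 to 19.3 TPM (−0.64), among 17 genes of the growth hormone and IGF axis (median −0.01, percentile 74.3). All 17 JAK-STAT components measured lay within 1.5-fold (median −0.05, percentile 44.4). The most abundant were JAK1, at 162 TPM uninjected and 157 TPM injected, and STAT5B, at 113 and 112 TPM.

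Skeletal genes differed by kind. The cartilage list had a median of 0.17 (95% interval 0.07 to 0.43), above all 10000 random lists, with 15 of 20 genes above 0 and 3 calls. The matrix genes MATN3 (0.75) and EPYC (0.70; 68.3 and 111 TPM) were higher, and NKX3-2, a transcription factor of early cartilage, was lower (−0.97). COL2A1, the main cartilage collagen gene, named after its value was seen, was at 1128 and 1286 TPM. The list of cartilage hypertrophy and bone had a median of −0.35 (95% interval −0.49 to 0.01) at percentile 0.03, while its calls went both ways: DLX6 (−0.91) and alkaline phosphatase, ALPL (74.9 and 49 TPM, −0.61), were lower, and MMP13 (0.61) and RUNX3 (0.60) were higher. ALPL lost its call under each of 3 other scalings, where its ratio lay between −0.58 and −0.56, and MMP13 and RUNX3 lost theirs with a pseudocount of 1 TPM, each at 0.55, which left calls in the lower direction alone. MATN3 lost its call there too, at 0.57. The joint interzone list had a median of −0.17 (−0.33 to −0.08) at percentile 0.92. GDF5, a growth factor of the forming joint, was lower at 24.6 and 14.6 TPM (−0.75), and OSR1 was higher at 56.8 and 102 TPM (0.85).

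Markers of other tissues also differed between the samples. Skeletal muscle genes had a median of 0.21 (95% interval 0.13 to 0.31), above all random lists, with 29 of 32 above 0 and 3 higher. These were MYF5, a regulator of muscle precursors, at 11.9 and 25.7 TPM (1.11), and the myosin genes MYLPF (0.66) and MYH7B (0.65). Schwann cell and nerve genes had a median of 0.11 at percentile 99.5, with 4 of 17 higher, among them STMN2 (0.71) and SOX10 (0.61; 0.58 and no longer called with a pseudocount of 1 TPM). Limited to genes with a mean of at least 5 TPM, that list had a median of 0.07 and was no longer outside the random range. Epidermis and feather placode genes had a median of −0.32 (−0.38 to −0.11), below all random lists, with 21 of 23 below 0 and 1 lower, the splicing regulator gene ESRP1 (−0.72). Erythrocyte genes had a median of −0.18 at percentile 0.24, with 4 of 17 lower. These were RHAG (−1.01), SLC4A1 (−0.85), the globin gene HBBR at 146 and 89.2 TPM (−0.71) and, named after its value was seen, HBZ (−0.70); globin genes have near-identical copies and their values are uncertain. The tendon and connective tissue list had a median of −0.11 at percentile 0.12, while its 2 calls were higher, OSR1 (0.85) and POSTN at 431 and 683 TPM (0.66). The melanocyte list had a median of −0.29 at percentile 2.42, with OCA2 lower (−0.92) among 7 genes. It lay at −0.01 when genes under 5 TPM were left out.

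Smooth muscle and pericyte genes had a median of 0.08 at percentile 97.3, with ACTG2 higher (0.85) among 11. Macrophage and leukocyte genes (28) and endothelial genes (19) held 0 calls, with medians of 0.01 at percentile 92.8 and −0.01 at percentile 79.3. Among their most abundant members were AIF1L at 91.2 and 101 TPM, CDH5 at 144 and 141 TPM, and ERG at 72.0 and 71.4 TPM.

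Genes of the interferon and antiviral response, measured because the vector is a replicating virus, included 0 higher and 4 lower among 23. The lower genes were the chemokine gene CCL19 (−0.96), IFI27L1 at 15.2 and 8.25 TPM (−0.87), the peptide transporter gene TAP1 (−0.72) and, named after its value was seen, OASL (−0.70). The list median of −0.15 lay at percentile 14.1. With a pseudocount of 1 TPM, CCL19 (−0.53) and TAP1 (−0.58) lost their calls.

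The 33 cell cycle genes all lay within 1.5-fold, with a median of −0.01 (95% interval −0.04 to 0.02) at percentile 54.6. PCNA, the replication clamp, was at 508 and 523 TPM, and CDK1, the mitotic kinase, at 344 and 334 TPM.

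Lists that track RNA quality and handling were mixed. All 13 mitochondrially encoded genes had ratios above 0, with a median of 0.33 (95% interval 0.19 to 0.40) above all random lists, and ND3 was higher at 258 and 519 TPM (1.01). Ribosomal protein genes had a median of 0.18 (0.02 to 0.24), also above all random lists, with RPS29 (0.88), RPL36 (0.72) and RPL38 (0.71) higher and RPLP1 lower (−0.64) among 60. Immediate early and heat shock genes (21) had a median of −0.07 at percentile 22 and 0 calls, with HSPA8 at 1339 and 1492 TPM and HSP90AA1 at 948 and 1005 TPM. Glycolysis and hypoxia genes (26) had a median of −0.06 at percentile 10.7, with EGLN3 lower (−0.67; −0.51 and no longer called with a pseudocount of 1 TPM). The 20 reference genes had a median of −0.01 at percentile 43.5 and 0 calls. EEF1A1 was at 13712 and 9880 TPM (−0.47) and ACTB at 6415 and 7549 TPM (0.23).

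**Figure D3:**
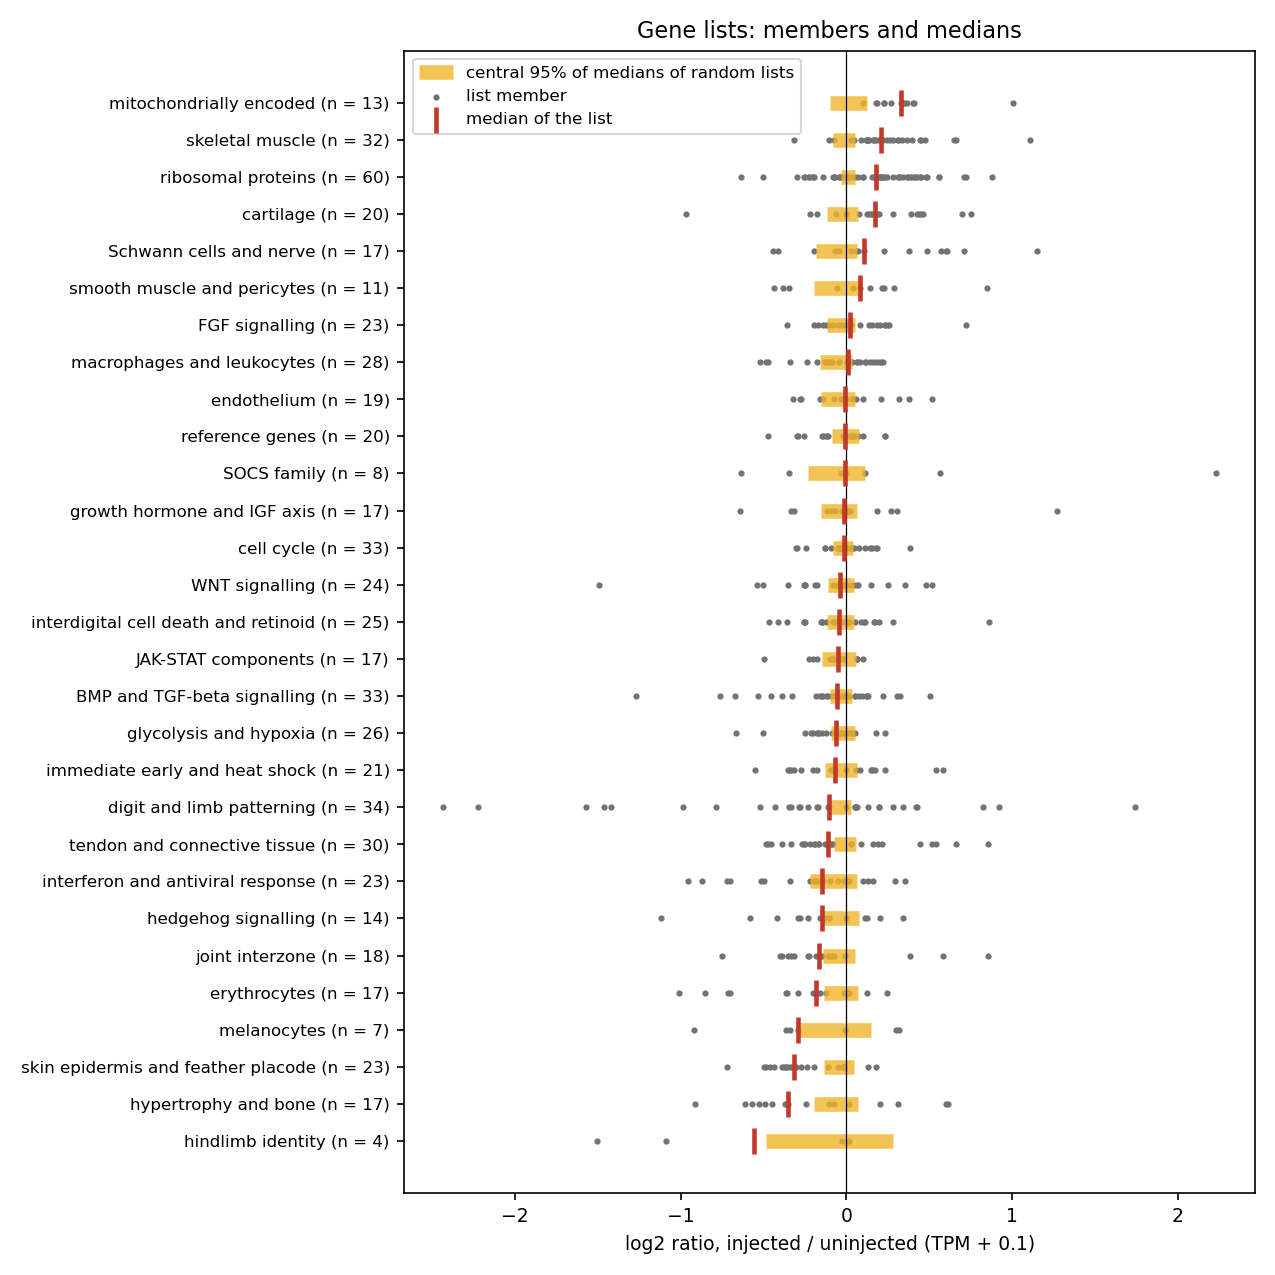
The log2 ratio of injected over uninjected wing (TPM + 0.1) is shown for the measured members (grey points) of each of 29 gene lists, with the list median (red bar) and the central 95% of the medians of 10000 random lists matched on abundance (yellow band). The medians of 5 lists lie above their band and those of 7 below it.

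Across the 29 lists, 5 medians lay above the central 95% of their random lists, 7 below and 17 within. In the simulated data, where each gene varied independently, 6 of 200 unchanged lists of 20 genes fell outside that range. Of 200 lists shifted by 0.2 on the log2 scale, 195 lay above it. These percentiles describe 2 libraries, and members of a list that share a tissue are not independent.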

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

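The tests in this part were chosen only after the results were seen. A pair of rows with no gene symbol drew attention because they were listed at 0 in the uninjected wing and stood above 100 TPM in the injected wing, outside the genes compared. ENSGALG00000052797 was at 562 TPM and ENSGALG00000026300 at 145 TPM in the injected wing. A failed estimate in the uninjected library may account for this: such failures would be found in both directions, and 0 rows were at 0 in the injected and above 100 TPM in the uninjected wing. At lower thresholds such genes were found in both directions, with 8 at 0 in the uninjected and 12 at 0 in the injected wing at 1 TPM or more, 5 and 2 at 5 TPM, and 3 and 1 at 10 TPM, so these counts do not decide it. Reads of the injected vector placed on related rows of the reference is another candidate explanation, for which the 2 rows would have to resemble the vector. No sequence of either was compared, so the explanations cannot be told apart.

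HOXA13 and HOXD13 were lower in the injected wing by more than 4-fold, at log2 ratios of −2.22 and −2.43. A bias of the library against Hox genes as a class would put the other Hox genes beyond 1.5-fold too. Those 30 genes had a median of 0.076 (95% interval −0.02 to 0.43), with 8 higher and HOXD12, HOXD11 and HOXC9 lower. This argues against such a bias. A bias tied to the sequence of single genes, such as their GC content, or one shared with other homeobox genes was not tested. Of other homeobox genes named here, MSX1, MSX2, NKX3-2, DLX6 and GSC were lower, Meis2a.2 was higher (0.82) and PITX1 lay within 1.5-fold. All but PITX1 were named because they passed 1.5-fold, so they do not show how homeobox genes differed as a class. No full set of homeobox genes was counted. A larger share of proximal and a smaller share of distal tissue in the injected sample may account for the pattern. Genes that were neither Hox genes nor on a fixed list were used. The 7 proximal genes had a median of 0.14 (−0.25 to 0.50), above the random range at percentile 99.1. The 3 distal genes had a median of −0.13, inside a random range of −0.40 to 0.26, too few to decide. All 13 distal genes that are not Hox genes had a median of −0.67, below all random lists. That list was written after many members had been seen, and 7 of the 13 were called lower. Its place among random lists is therefore no independent support for a smaller share of distal tissue. FGF8 and FGF4, known from the apical ridge at the distal tip, were higher (0.92 and 1.74). Whether their transcripts came from the ridge in these samples was not tested, so they do not decide it either. Lists fixed beforehand also differed between the samples, with skeletal muscle at 0.21 and Schwann cells at 0.11 above their random range and epidermis at −0.32 and erythrocytes at −0.18 below it, but mitochondrially encoded genes at 0.33 and ribosomal protein genes at 0.18 were above theirs too, so these lists separate neither distal from proximal tissue nor tissue content from RNA quality. A response of the digit region to SOCS2 stays open as well and cannot be told apart from uneven tissue, because the design holds 1 library per group and no wing injected with a vector lacking SOCS2.

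NDUFB7, MRPS12 and OPA3 were lower in the injected wing, at log2 ratios of −1.82, −1.52 and −1.84. A fall of nuclear genes for complex I and the mitochondrial ribosome as a class would put their medians beyond 1.5-fold, but 32 complex I genes had a median of 0.06 and 68 mitochondrial ribosomal genes one of −0.068 (95% interval −0.15 to 0.00). A loss of short, abundant transcripts in the injected library would lower ribosomal protein genes, whose median was 0.18 (0.02 to 0.24). The first medians argue against a fall of either class as a whole, and do not bear on OPA3, which belongs to neither. The ribosomal median argues against a general loss of short, abundant transcripts, unless those genes rose for another reason. It does not cover less abundant transcripts, and MRPS12 and OPA3 were at 48.9 and 17.3 TPM in the uninjected wing. A GC bias acting on single genes and a difference between the wings that is specific to these genes were not tested.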

How the results depend on the processing

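Alternatives with pseudocounts of 1 and 0.01 TPM, with short RNAs kept and with symbols only were chosen after the data were seen. Of the values recomputed, 0 list medians or named genes that passed their threshold changed direction. Named genes were not recomputed with short RNAs kept or with symbols only, and 64 of 87 values remained at a minimum mean of 5 TPM. For single named genes, 708 values stayed on their side of the threshold, 48 lost their call and 4 gained one; 35 of the losses came from the 2-fold rule. With a pseudocount of 1 TPM, SOCS3, MATN3, MMP13, RUNX3, CCL19, TAP1, SOX10 and EGLN3 lost theirs. The 3 scalings moved log2 ratios by less than 0.05. The counts of higher and lower genes were 831 and 1298 with no filter on low values, 122 and 292 at a minimum mean of 5 TPM, 70 and 207 with the 2-fold rule, 186 and 432 with a pseudocount of 1 TPM, and 186 and 353 with symbols only; these follow from more or fewer genes passing. The split was 382 and 584 with median-of-ratios scaling, 364 and 597 with upper-quartile and 383 and 581 with trimmed-mean scaling. Medians that moved inside the random range were those of hindlimb identity with no filter (−0.18), of melanocytes with no filter (−0.16), at 5 TPM (−0.0061) and with short RNAs kept (−0.29), and of Schwann cells at 5 TPM (0.068). Medians that moved outside it were those of hedgehog signalling at 5 TPM (−0.15), with the abundance trend removed (−0.12) and with a pseudocount of 1 TPM (−0.15), and of smooth muscle with a pseudocount of 1 TPM (0.081). The cause was not tested. Total-count scaling, halved counts and an interval beyond 1, which need counts, were not run. The length trend was not run either, as transcript length was not analysed here. No paired analysis was possible because each group holds 1 library and the groups share 1 replicate number. Unknown depth limits what can be said of genes at low TPM, where calls were most frequent.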

Other observations

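The groups and genes in this part were chosen after their values were seen. Histone genes had 5 of 24 members lower and 0 higher, with a median log2 ratio of −0.25 (95% interval −0.45 to 0.05): HIST1H46L2 (−2.44), HIST1H46 (−1.32), HIST2H4B (−1.09), H2A-IX (−0.88) and HIST1H3H (−0.62). These families hold near-identical copies and many of their transcripts lack a poly(A) tail, so their values are uncertain. The histone median lay within 1.5-fold, though at percentile 0.24 of random lists. In other groups too, single members passed 1.5-fold while the median did not. Of 32 complex I genes, 28 lay within 1.5-fold and the median of 0.06 was above the random range, while NDUFB7 (−1.82), NDUFS5 (−0.95) and NDUFB2 (−0.63) were lower and NDUFA1 (0.80) was higher. Of 68 genes of the mitochondrial ribosome, 63 lay within 1.5-fold and the median was inside the random range, while MRPS12 (−1.52), MRPL43 (−1.31), MRPS16 (−1.12), MRPL28 (−0.60) and MRPL41 (−0.59) were lower and 0 genes were higher.

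Among single genes, the matrix genes MGP (54.5 and 102 TPM, 0.91) and PRELP (94.3 and 153 TPM, 0.70) were higher, as were the guidance cue gene NTN1 (0.93), the CNTF receptor gene CNTFR (0.77), and SIM1 (0.78) and MSC (0.73), transcription factors found in muscle precursors. The transcription factor genes GSC (46.2 and 26.1 TPM, −0.82) and CITED2 (−1.03) were lower.

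Across the 32 Hox genes compared, the log2 ratio had a Spearman rho of −0.56 with paralogue group. Without HOXA13 and HOXD13 it was −0.47 over 30 genes, which still held HOXA11, HOXD11 and HOXD12. The fall was no even gradient. Up to group 10, ratios ran from −0.11 to 0.35 in cluster A and from −0.02 to 0.43 in cluster D. Neighbouring Hox genes are regulated together and are not independent. A list of distal limb genes that includes HOXA13, HOXD13 and HOXD12 had a median of −0.83 over 16 genes, and −0.67 over the 13 that are not Hox genes. A list of proximal limb genes had a median of 0.22 over 20 genes, and 0.14 over the 11 that are not Hox genes. Both lists were written after many members had been seen.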
